A study of Arabidopsis thaliana with 10 samples.

How the data were processed

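Gene expression was measured in leaves of Arabidopsis thaliana by sequencing of RNA libraries made, per the labels, with a Lexogen QuantSeq kit. Such kits read a short stretch of each transcript, though the labels leave open which kit of the maker was used, and no correction for gene length was applied. The 10 libraries fall into 5 labelled groups of 2, with each sample's group and replicate number taken from its title. The labels do not say that the 2 libraries of a group came from separate plants or separate growth batches, so p-values measure only the spread between these libraries, which may be technical.

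The authors deposited raw read counts per gene, 1 file per library, and per the submitters' processing notes Bowtie2, edgeR and the TAIR10 genome were used. Versions, the program that counted reads and its strand setting are not given in the sources used here. The deposited counts are whole numbers. Each file lists 33028 rows, no row lacks a name, and the totals run from 14187505 to 24496672 counts per library. No library was found to be a copy of another, as the counts of the 2 libraries of a group differed by more than counting noise (chi-square of 33.2 to 241.8 per gene). Separate preparations of one sample would differ so too, and this does not show that the libraries are separate plants.

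The name written in the header of a deposited count file and the label of its sample disagreed for 8 of the 10 libraries. Only the libraries labelled Col D0 carried the same name in both. The pair labelled RanT27N D0 carries the header RanG22V D0, the pair labelled RanG22V D0 carries RanG22V D3, the pair labelled RanT27N D3 carries RanT27N D0, and the pair labelled RanG22V D3 carries RanT27N D3. All groups here follow the labels, and each group is written as the pair or the libraries labelled with that name.

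Rows carry gene names, which were paired with locus codes through the gene table of the TAIR10.1 reference. Of the rows, 32577 (98.6%) were paired. A further 429 rows share their name with another row and were kept under a numbered name, without a locus. The submitters' build differs from that reference, so no coordinates are given. SEN1 is such a shared name and RAN4 did not reach the filter on low counts, so neither has a value.

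Genes were tested in R 4.3.3 with edgeR 4.0.16. Rows were kept by filterByExpr, which left 21475 genes, libraries were scaled by TMM, and 1 model of 5 group means was fitted to all 10 libraries, so that all groups share an estimate of the spread (biological coefficient of variation 45%). Each comparison used the quasi-likelihood test with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. Standard errors are the fold change divided by the root of the test statistic. CPM are the values of edgeR's cpm function with the TMM-scaled library size, given as mean ± SD over the 2 libraries of a group. Where all libraries of a group had 0 counts, the fold is a lower bound computed with 3 counts in each library of that group, a floor that covers counting error only. Reads carry no molecular identifiers in the files, so they are not independent molecules.

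The gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said otherwise. There were 19 lists with 354 members, of which 342 could be used (336 distinct genes). They cover senescence, chlorophyll breakdown, dark and carbon starvation, light harvesting and the photosystems, the Calvin cycle, chlorophyll synthesis, salicylic acid, jasmonate, abscisic acid, ethylene, autophagy, Ran and nuclear transport, the circadian clock, glucosinolates, flavonoids and anthocyanins, nitrogen remobilisation, heat shock, leaf cell types and other organs. List members are general knowledge and were not chosen on these samples. Lists were tested against the other genes with camera (limma 3.58.1) on log2 CPM with a pseudocount of 2 and a preset correlation of 0.01, then with an estimated correlation, each adjusted over the 19 lists of a comparison. With the estimated correlation no list kept its call in any comparison. A further planned test, fry, asks whether a list changed on its own, not against the other genes. For RanG22V D0 vs Col D0 it gave adjusted p = 0.000674 for dark and starvation and 0.00159 for the Calvin cycle. It also gave 0.000721 for the other organs, with 0 members called. For RanT27N D3 vs RanT27N D0 and RanT27N D0 vs Col D0 the salicylic acid list had 0.0756 and 0.081 by fry. Fitted values of genes at 0 in a group depend on the pseudocount. With such genes held at their bound, 3 of 152 list medians moved.

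The rule for named genes takes for each comparison the 6 largest increases and the 6 largest decreases among called genes with a mean CPM of at least 10 in the higher group and no overlap between the libraries of the 2 groups, up to 4 called members of each list with the smallest adjusted p, and a set of Ran, senescence, defence and photosynthesis genes given whether called or not. For the interaction it takes 4 in each direction. Of the 170 genes so named, 38 overlap another annotated gene, and since the strand setting of the counting is not known their reads cannot be told apart from those of the neighbour. RAN1 to RAN3, the RBCS genes, the LHCB genes and the ATG8 genes have close copies, so how reads were divided among the copies is uncertain.

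The fit was tested on simulated counts drawn for the real genes from their means, dispersions and library sizes. With 200 genes changed, 100 of them 2-fold and 100 4-fold, 0% of the 2-fold and 0% to 1% of the 4-fold changes were recovered in the 9 comparisons. The larger sizes of 16- and 64-fold, with 50 genes of each of the 4 sizes, were added after that low recovery was seen. With so few genes changed, most changes of 4-fold or less were missed, which need not hold where many more genes differ. For RanG22V D0 against RanT27N D0 (20771 genes) 0% of the 2-fold changes, 16% of the 4-fold, 68% of the 16-fold and 84% of the 64-fold changes were recovered, with 3 false calls. For RanT27N D3 against Col D0 (20822 genes) the shares were 0%, 14%, 70% and 80%, with 4 false calls. Over the 9 comparisons 3.4% to 8.4% of the edgeR calls were false, in part above the threshold of 5%. The simulation gave all groups the same spread and no replicate effect. In the data the SD of the log2 replicate difference ran from 0.89 in RanG22V D0 to 1.34 in Col D0. The shares of false calls in the data may therefore differ. DESeq2 1.42.0 on the first of these designs (21475 genes) recovered 10%, 44%, 88% and 98%, with 58 false calls, 32.6% of its calls. That share is above the threshold of 5%. It comes from 1 simulated comparison with 200 genes changed, so the share of false calls in its larger counts on the data is not known.

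The alternatives were DESeq2 size factors in place of TMM, the DESeq2 Wald test, no filter on low counts, a filter of at least 5 CPM in 2 libraries, a term for the replicate number, leaving out each library in turn, fitting only the libraries compared, and group names taken from the file headers. After seeing the data, a fit without ribosomal RNA (14 rows) and organelle genes (124 rows) and a fit of the 6 libraries labelled Col D0, RanT27N D0 and RanT27N D3 with the replicate term were added. Where leaving out a library left a group with 1, that lone library was assumed to vary like the other groups.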

Results

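RNA was profiled in the fifth and the sixth leaf of 4-week-old Arabidopsis plants grown at 22 °C with 16 h of light and 8 h of darkness. The plants were the wild type Col and lines that overexpress RanT27N or RanG22V. Ran is a small GTPase of nuclear transport, and the labels describe RanT27N as its GDP form and RanG22V as its GTP form. Leaves of the lines were sampled on day 0 (D0) and after 3 days in darkness (D3), and Col leaves on day 0. Each of the 5 groups has 2 libraries. Total counts were 21746547 and 20739240 for the libraries labelled Col D0, 22237249 and 24496672 for RanT27N D0, 21877905 and 17886155 for RanG22V D0, 17730541 and 20101281 for RanT27N D3 and 14187505 and 17539032 for RanG22V D3. Ribosomal RNA took 8.76% of the counts of replicate 2 labelled RanG22V D0 and 17.39% to 24.85% of the others.

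The Ran genes and the genes that respond to darkness were read first, since they bear on the labels. RAN1 stood at 346.5 ± 127.3 CPM (SD, n = 2) in the pair labelled Col D0, 590 ± 42.2 in RanT27N D0, 882 ± 44.0 in RanG22V D0, 1426 ± 130.6 in RanT27N D3 and 1174 ± 125.7 in RanG22V D3. RAN3 was at 46.4 to 57.3 CPM in the 6 libraries labelled D0 and at 103.1 to 123.8 CPM in the 4 labelled D3. By the file headers these 4, which were also the highest in RAN1, are the libraries of the RanT27N line on both days. Reads from the 3′ end would miss a transgene that lacks the gene's own end, and the Ran copies are nearly alike, so these counts need not show the transgene. The senescence protease gene SAG12 was at 507.5 and 756.4 CPM in the libraries labelled RanG22V D0 and at 139 and 438.8 CPM in those labelled RanG22V D3, against at most 1.22 CPM in the 6 others. ASN1, an asparagine synthetase gene known for its induction in darkness, was at 1162 ± 456.3 CPM in RanG22V D0 and 26.7 ± 22.5 in RanG22V D3, but at 0.228 ± 0.153 CPM in RanT27N D3. The median log2 CPM of the dark and starvation list was 6.77 and 6.24 in the libraries labelled RanG22V D0, 4.14 and 4.29 in RanG22V D3, and 2.76 to 3.80 in the 6 others, which include both labelled RanT27N D3. The Calvin cycle list ran the other way, with medians of 5.02 and 5.35 in RanG22V D0, 5.85 and 6.16 in RanG22V D3 and 8.07 to 9.09 elsewhere. The file headers give the pairs labelled RanG22V D0 and RanG22V D3 as the 2 sampled after darkness, and these are the pairs with the higher dark and starvation medians and the lower Calvin cycle medians. Directions in every comparison are those of the labels, so a difference by labelled line or day need not be one of line or darkness.

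**Figure D1:**
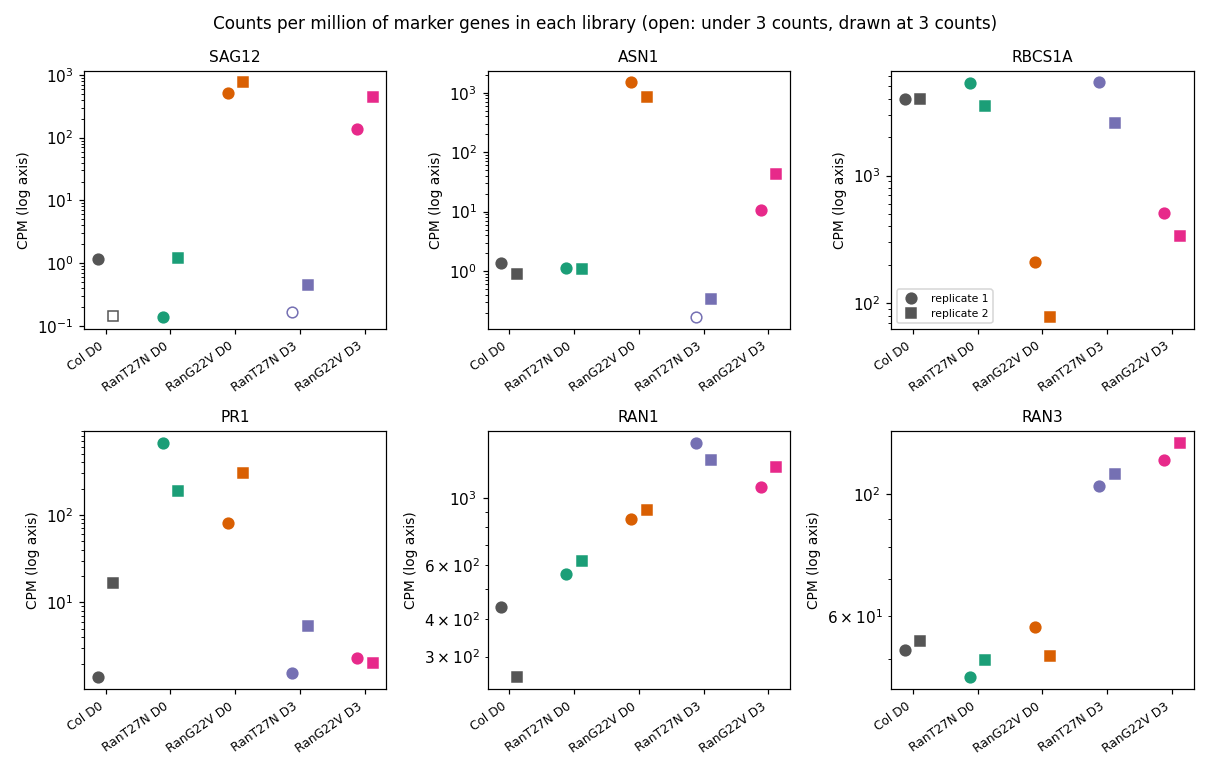
CPM (log axis) of SAG12, ASN1, RBCS1A, PR1, RAN1 and RAN3 in each of the 10 libraries, grouped by label, with circles for replicate 1 and squares for replicate 2; open symbols are libraries with under 3 counts, drawn at 3 counts. SAG12 reaches 507.5 and 756.4 CPM in the libraries labelled RanG22V D0 and stays at or below 1.22 CPM in those labelled Col D0, RanT27N D0 and RanT27N D3.

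**Figure D2:**
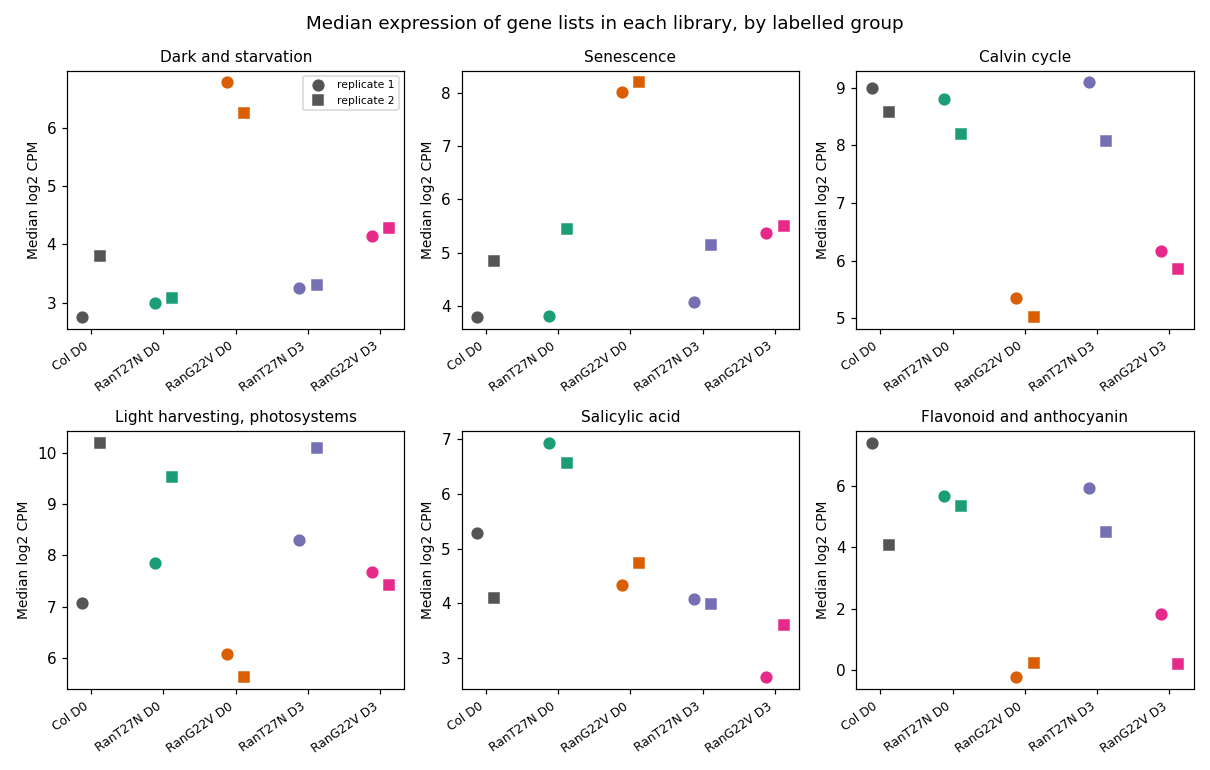
Median log2 CPM of 6 gene lists in each of the 10 libraries, grouped by label, with circles for replicate 1 and squares for replicate 2. The Calvin cycle medians of the pairs labelled RanG22V lie between 5.02 and 6.16, below the 8.07 to 9.09 of the other 6 libraries.

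The comparison of RanT27N D3 with RanT27N D0 asks, by its labels, how 3 days of darkness acted in the Ran-GDP line. Most of the called genes were lower in the pair labelled D3, and 3 of them belong to the salicylic acid list. DLO1, a salicylic acid hydroxylase gene, was at 1.47 ± 0.378 CPM against 241.8 ± 168.9 (log2 fold change -7.35 ± 0.86 SE, adjusted p = 0.0191 in edgeR's quasi-likelihood test, n = 2). AIG1, known for its induction by bacterial avirulence, was 193.2-fold lower at 0.749 ± 0.209 CPM, and PR5, a pathogenesis-related gene, 61.1-fold lower at 15.3 ± 5.64 CPM. FMO1, which makes the immune signal N-hydroxypipecolic acid, AT2G44240, AT1G51860 and AT5G55150 were nearly without counts in the pair labelled D3, with means of 0.0602, 0.0301, 0.0280 and 0.339 CPM, against 19.9, 13.9, 12.4 and 103.9 CPM. SDR4 was 250.2-fold lower. DLO1, PR5, AIG1 and AT5G55150 were also higher in the pair labelled RanT27N D0 than in Col D0, so that pair enters both differences. Between RanT27N D3 and Col D0 the salicylic acid list had a median log2 fold change of -0.17, with 0 genes called. By the file headers this comparison sets RanT27N D0 against RanG22V D0, both before darkness.

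Of the 29 salicylic acid genes tested, 3 were lower and 0 higher, against 13 lower when adjusted over the list alone, with a median log2 fold change of -1.28. That list was lower by camera with the preset correlation (adjusted p = 4.56e-09) and not with the estimated one (adjusted p = 0.411 with an estimated correlation). PR1 was at 3.50 ± 2.74 against 428.6 ± 338.5 CPM and missed the threshold (adjusted p = 0.0809 by edgeR). In the senescence list SAG13 and WRKY75 were lower, by log2 fold changes of -2.74 ± 0.39 and -3.34 ± 0.55, 2 of 25 genes and also 2 adjusted over the list alone. All 5 genes that were higher are named here. They were AT5G47590 (6.49-fold), AT5G16250 (4.58-fold), SQE6 (4.33-fold), a squalene epoxidase gene, CYP81F2 (4.25-fold), of indole glucosinolate synthesis, and AT5G56590 (3.16-fold). With a replicate term in the 6 libraries labelled Col D0, RanT27N D0 and RanT27N D3, an alternative chosen after seeing the data, 44 genes were called, 26 of them among the 74 called here, and these 5 genes, FMO1, SDR4, AT2G44240 and WRKY75 were not called.

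In the dark and starvation list 0 of 22 were called, 1 was lower adjusted over the list alone, and the median log2 fold change was 0.30 (camera adjusted p = 0.787). Of the 21 Calvin cycle genes 0 were called, also 0 adjusted over the list alone, with a median of 0.14. RBCS1A, of the small subunit of Rubisco, was at 3968 ± 1962 against 4417 ± 1250 CPM. With the preset correlation, light harvesting (median 0.50, camera adjusted p = 0.0235, and adjusted p = 0.913 with an estimated correlation), jasmonate (median 0.78, camera adjusted p = 0.0417, and adjusted p = 0.913 with an estimated correlation) and glucosinolate genes (median 0.71, camera adjusted p = 0.0148, and adjusted p = 0.709 with an estimated correlation) were higher as lists, with 0 members called and 0 adjusted over the list alone. Abscisic acid genes had a median of 1.12 with 0 of 15 called and 0 adjusted over the list alone (camera adjusted p = 0.00215, and adjusted p = 0.709 with an estimated correlation). RAN1 had a log2 fold change of 1.27 ± 0.38 (adjusted p = 0.289) and RAN3 of 1.14 ± 0.25 (adjusted p = 0.136), neither called by edgeR. In all, 74 of 21475 genes were called, 5 higher and 69 lower. That count was 0 without either library labelled RanT27N D3, 43 and 35 without replicates 1 and 2 labelled RanT27N D0, 20 without either labelled RanG22V D0, 32 without either labelled RanG22V D3, 180 and 177 without replicates 1 and 2 labelled Col D0. It reached 0 with only the 4 libraries compared, 563 without a filter and 563 by DESeq2.

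The comparison of RanG22V D3 with RanG22V D0 asks, by its labels, the same of the Ran-GTP line. Its pairs carry the file headers RanT27N D3 and RanG22V D3, so by these it sets the lines side by side after darkness. The genes called lower in the pair labelled D3 included 12 of 22 dark and starvation and 6 of 24 autophagy genes. They also included 7 of 25 senescence and 6 of 29 salicylic acid genes. None of these lists kept its call with an estimated correlation. ASN1 was 43.5-fold lower (log2 fold change -5.44 ± 0.72, adjusted p = 0.00667 by edgeR, n = 2), DIN4 and LTA1, both of branched-chain amino acid breakdown, were 13.6-fold and 8.03-fold lower, and TPS11, a trehalose phosphate synthase gene, was 10.5-fold lower. Of the 22 dark and starvation genes 12 were lower and 0 higher (15 lower adjusted over the list alone, median log2 fold change -2.50, camera adjusted p = 2.9e-09, and adjusted p = 0.15 with an estimated correlation). Autophagy genes fell as well, 6 of 24 (16 adjusted over the list alone, median -1.10, camera adjusted p = 1.55e-07, and adjusted p = 0.313 with an estimated correlation). Among them ATG8H was at 9.20 ± 2.93 against 117.1 ± 22.2 CPM and ATG7, an activating enzyme of the pathway, at 11.6 ± 2.92 against 80.0 ± 5.24 CPM.

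Of the 25 senescence genes 7 were lower (9 adjusted over the list alone, median -1.20, camera adjusted p = 1.18e-05, and adjusted p = 0.15 with an estimated correlation). WRKY6 was 9.79-fold, SAG13 7.47-fold, SAG14 4.925-fold and PPDK 4.54-fold lower. SAG12 (288.9 ± 212 against 631.9 ± 176 CPM), ORE1 and NAP, NAC factors of senescence, were not called, with log2 fold changes of -1.13, -1.46 and -1.22. The chlorophyll breakdown genes MES16 and NYE1, the latter a magnesium dechelatase gene, were 7.71-fold and 3.94-fold lower, 2 of 13 called (6 adjusted over the list alone, camera adjusted p = 0.00995, and adjusted p = 0.397 with an estimated correlation). Salicylic acid genes fell, 6 of 29 (10 adjusted over the list alone, median -1.73, camera adjusted p = 3.7e-06, and adjusted p = 0.19 with an estimated correlation), among them PR1 (2.18 ± 0.187 against 190.3 ± 154.8 CPM), UGT74F2, FMO1 and GRX480. Nitrogen remobilisation genes were lower in 4 of 13 cases, with GDH2 8.02-fold and the nitrate transporter gene NRT1.5 4.95-fold lower (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000907, and adjusted p = 0.19 with an estimated correlation). The ethylene synthesis gene ACS2 was 17.5-fold lower and the jasmonate repressor gene JAZ8 16.1-fold lower.

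Higher in the pair labelled D3 were 2 of 14 glucosinolate genes, BAT5 (13.5-fold) and CYP83A1 (8.07-fold), with 10 higher and 1 lower adjusted over the list alone. The median of this list was 2.3, or 2.03 with a gene at 0 held at its bound (camera adjusted p = 1.18e-05, and adjusted p = 0.19 with an estimated correlation). RANGAP1, the GTPase-activating protein of Ran, was 2.56-fold higher and RAN3 2.21-fold higher, 2 of 18 Ran and transport genes and also 2 adjusted over the list alone (median 0.49, camera adjusted p = 0.0132, and adjusted p = 0.397 with an estimated correlation). Light harvesting and photosystem genes had a median of 1.48 with 0 of 48 called and 0 adjusted over the list alone (camera adjusted p = 1.55e-07, and adjusted p = 0.455 with an estimated correlation). Calvin cycle and chlorophyll synthesis genes had medians of 0.77 and 0.72 with 0 called, and 0 and 6 higher adjusted over the list alone (camera adjusted p = 0.00385 for both, and adjusted p = 0.563 and 0.298 with an estimated correlation). The largest increases were an AACT1 row (61.8-fold), AT1G59950 (30.7-fold), MLP43 (30.1-fold), PLAT2 (25.4-fold), AT5G22580 (23.1-fold) and AT1G52190 (16.2-fold). Without a single count in the pair labelled D3 were AT1G17030, at least 249.8-fold lower, NCED2, an abscisic acid synthesis gene, at least 145.4-fold lower, AT1G15385, at least 142.3-fold lower, ADPG1, a polygalacturonase gene, at least 98.2-fold lower, and AT3G53040, at least 96.0-fold lower. Over all genes 846 were called, 251 higher and 595 lower. The count was 27 and 28 without replicates 1 and 2 labelled RanG22V D3, 165 without either labelled RanG22V D0, 1464 and 1452 without replicates 1 and 2 labelled Col D0, 2107 without a filter. It reached 3607 with only the 4 libraries compared and 2583 by DESeq2.

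**Figure D3:**
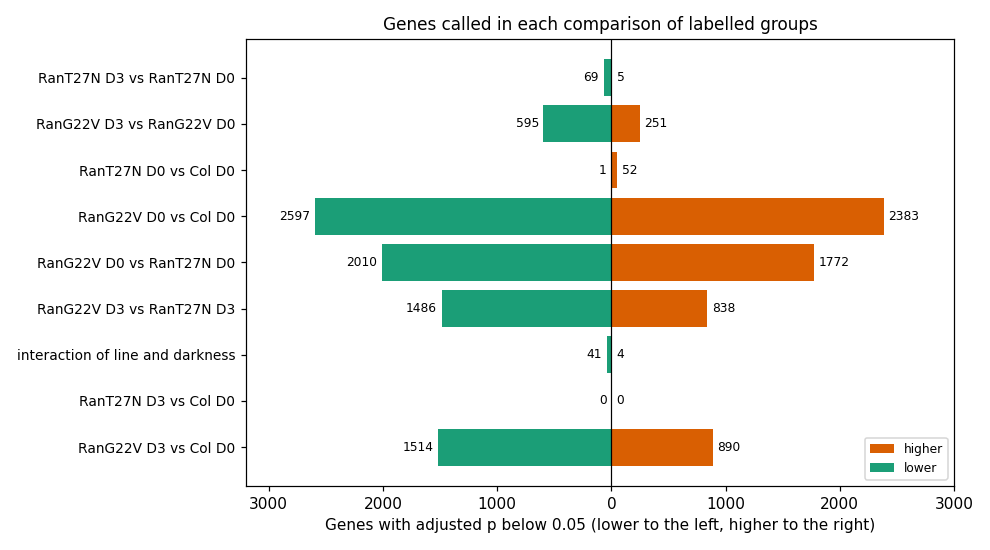
Number of genes called by edgeR (adjusted p below 0.05) in each comparison of labelled groups, with genes that were higher in the group named first to the right and genes that were lower to the left. The comparison of RanG22V D0 with Col D0 has the most calls (2383 higher and 2597 lower) and that of RanT27N D3 with Col D0 has 0.

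The comparison of RanT27N D0 with Col D0 asks, by its labels, what the Ran-GDP form changes in leaves before darkness. The file headers give it as RanG22V D0 against Col D0, which would make it the Ran-GTP form before darkness. Nearly all called genes were higher in the pair labelled RanT27N D0, and 2 of them belong to the salicylic acid list. DLO1 was 79.5-fold higher (log2 fold change 6.31 ± 0.81, adjusted p = 0.024 by edgeR, n = 2), PR5 58.8-fold (adjusted p = 0.0456), AIG1 82.9-fold (adjusted p = 0.0105) and AT2G18193 129.1-fold (adjusted p = 0.0125). BIP3, a chaperone gene of the endoplasmic reticulum, was 63.9-fold higher at 134.7 ± 86.8 CPM. AT2G04050 had 0 counts in the pair labelled Col D0 and was at least 81.1-fold higher, and AT5G55150 was at 103.9 ± 32.9 against 0.0499 CPM. SAG13 was 7.14-fold higher, the one called of 25 senescence genes (2 higher and 1 lower adjusted over the list alone). Of the 29 salicylic acid genes 2 were higher and 0 lower (12 higher adjusted over the list alone, median log2 fold change 1.05, camera adjusted p = 2.8e-08, and adjusted p = 0.485 with an estimated correlation). PR1 was at 667.9 and 189.2 CPM against 1.397 and 16.7 CPM and was not called (adjusted p = 0.165).

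Of the other 18 lists 0 were called by camera in this comparison. The Calvin cycle median was -0.15 and the dark and starvation median -0.27, with 0 members of either called (0 and 1 adjusted over the list alone). RAN1, RAN2 and RAN3 had log2 fold changes of 0.77 ± 0.37, 0.85 ± 0.28 and -0.14 ± 0.25 and were not called. Between the 2 libraries labelled Col D0 LHCB1.1, a light-harvesting gene, differed from 21.2 to 962.8 CPM, and between those labelled RanT27N D0 from 76.0 to 2763 CPM. In all 53 genes were called, 52 higher and 1 lower. With a replicate term in the 6 libraries labelled Col D0, RanT27N D0 and RanT27N D3, 27 were called, 16 of them among these 53, and AT2G04050 was not called. The count was 23 and 0 without replicates 1 and 2 labelled Col D0, 21 without replicate 2 labelled RanT27N D0, 21 without either labelled RanG22V D0, 28 and 27 without replicates 1 and 2 labelled RanG22V D3, 32 without either labelled RanT27N D3. It reached 0 with only the 4 libraries compared, 34 with the stricter filter, 391 without a filter and 402 by DESeq2.

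The comparison of RanG22V D0 with Col D0 asks, by its labels, what the Ran-GTP form changes before darkness, and it held the most calls. In the file headers it is RanG22V D3 against Col D0, so that line and darkness both differ. In the pair labelled RanG22V D0 35 of 48 light harvesting and 17 of 21 Calvin cycle genes were called lower, and 15 of 22 dark and starvation, 13 of 25 senescence and 16 of 24 autophagy genes higher, and none of these lists kept its call with an estimated correlation. SAG12 was at 631.9 ± 176 against 0.574 ± 0.811 CPM (log2 fold change 10.06 ± 1.57, adjusted p = 0.00221 by edgeR, n = 2), and ORE1 and NAP were 43.0-fold and 39.9-fold higher. Of the 25 senescence genes 13 were higher and 2 lower, also adjusted over the list alone (median 1.93, camera adjusted p = 9.84e-05, and adjusted p = 0.127 with an estimated correlation), among them SAG13 (48.4-fold), WRKY75 (29.9-fold), WRKY45 (19.8-fold) and PPDK (7.21-fold). Dark and starvation genes rose in 15 of 22 cases, also 15 adjusted over the list alone (median 3.21, camera adjusted p = 1.28e-08, and adjusted p = 0.127 with an estimated correlation). ASN1 was 1037-fold, GDH2 57.3-fold, DIN4 22.3-fold and LTA1 18.4-fold higher. Autophagy genes rose in 16 of 24 cases, also 16 adjusted over the list alone (median 1.83, camera adjusted p = 1.54e-08, and adjusted p = 0.27 with an estimated correlation). ATG8H was 34.0-fold, ATG8E 28.8-fold, ATG7 22.3-fold and ATG8A 8.89-fold higher.

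In the chlorophyll breakdown list 7 of 13 were higher and 2 lower (8 and 3 adjusted over the list alone, median 1.95, camera adjusted p = 0.0228, and adjusted p = 0.321 with an estimated correlation). MES16 (85.95-fold), NYE2 (log2 fold change 5.13) and NYE1 (20.9-fold) were higher and the chlorophyllase gene CLH1 was 159.2-fold lower. Of 16 chlorophyll synthesis genes 8 were lower (10 adjusted over the list alone, median -1.22, camera adjusted p = 0.000466, and adjusted p = 0.27 with an estimated correlation), among them PORC (11.2-fold), CHLG (10.6-fold), CHLM (6.65-fold) and DVR (19.0-fold). Calvin cycle genes fell in 17 of 21 cases (19 adjusted over the list alone, median -3.71, camera adjusted p = 2.26e-10, and adjusted p = 0.27 with an estimated correlation). PRK, phosphoribulokinase, was 30.5-fold lower, RBCS1A 27.7-fold, HCEF1 26.35-fold, PGK1 8.93-fold and RCA, the Rubisco activase gene, 8.32-fold. Light harvesting and photosystem genes fell in 35 of 48 cases (44 adjusted over the list alone, median -3.35, camera adjusted p = 3.07e-12, and adjusted p = 0.275 with an estimated correlation). PSBS was 42.3-fold, PETC 10.4-fold and ATPC1 5.18-fold lower. LHCB1.1 was not called (adjusted p = 0.156).

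Of 12 flavonoid and anthocyanin genes 11 were called (12 adjusted over the list alone, median -6.61, camera adjusted p = 8.88e-06, and adjusted p = 0.275 with an estimated correlation). LDOX was 431.2-fold, TT19 106.9-fold, FLS1 82.5-fold and UGT75C1 33.2-fold lower. Of 14 glucosinolate genes 13 were lower, also 13 adjusted over the list alone (median -4.58, camera adjusted p = 3.83e-08, and adjusted p = 0.127 with an estimated correlation). CYP79B3 was 70.9-fold, BAT5 41.6-fold and BCAT4 38.1-fold lower. Of 18 jasmonate genes 12 were lower (13 adjusted over the list alone, median -3.14, camera adjusted p = 1.35e-05, and adjusted p = 0.275 with an estimated correlation), among them the synthesis genes AOC2 (141.3-fold) and OPR3 (32.2-fold), the repressor gene JAZ5 (22.6-fold) and MYC2 (9.07-fold). Of 13 nitrogen remobilisation genes 6 were higher and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.0346, and adjusted p = 0.275 with an estimated correlation). NRT1.5 was 89.9-fold higher and GLN2, plastid glutamine synthetase, 17.8-fold lower.

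Of the 8 lists without a call by camera in this comparison, 4 held called members in both directions. For salicylic acid 4 of 29 were higher (UGT74F2 32.3-fold, FMO1 29.3-fold, EPS1 4.60-fold and, among them, PR1 21.1-fold) and 2 lower (EDS5 5.62-fold), also 4 and 2 adjusted over the list alone, with a median of -0.23, a mean of 0.40 and the test's direction upward. For abscisic acid 5 of 15 were higher and 3 lower (6 and 5 adjusted over the list alone), with a median of 0.70 and a mean of -0.15, and with the phosphatase genes SAG113 35.5-fold and HAI2 3.87-fold higher and COR15A 156.2-fold and RD29A 39.5-fold lower. For ethylene 3 of 11 were higher and 3 lower (5 and 4 adjusted over the list alone). ACS2 was 30.5-fold and EBF2 5.99-fold higher and ERF2 4.09-fold lower. For Ran and nuclear transport 4 of 18 were higher and 1 lower, also 4 and 1 adjusted over the list alone. RAN1 (2.55-fold, adjusted p = 0.0308), RAN2 (3.05-fold), the exportin gene XPO1B (3.40-fold) and the importin gene IMPA4 (1.94-fold) were higher and RANGAP1 was 8.45-fold lower. None of the 13 clock genes and none of 6 heat shock genes was called, also 0 adjusted over the list alone, with medians of -0.60 and -0.37, while the test's direction was upward in both lists. Of 6 leaf cell type genes, SUC2 of phloem companion cells (9.55-fold) and ATML1 of the epidermis (2.61-fold) were lower, 2 also adjusted over the list alone, with a median of -0.97 (camera adjusted p = 0.0602). Of 6 genes of other organs 0 were called, also 0 adjusted over the list alone (median 1.12, camera adjusted p = 0.212).

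With 0 counts in both libraries labelled Col D0 were AT3G04320, at least 310.3-fold higher, AT1G20180, at least 261.8-fold, AT3G05400, at least 241.7-fold, CYP709B2, at least 234.7-fold, UMAMIT25, an amino acid transporter gene, at least 211.3-fold, and AO4, at least 201.7-fold. With 0 counts in both libraries labelled RanG22V D0 were AT4G35160, at least 241-fold lower, EXPA5, an expansin gene, at least 151.9-fold, ASG8, at least 146.5-fold, and AT1G73325, AT1G66940 and AT3G29590, at least 142.5-, 139.2- and 137.5-fold. Over all genes 4980 were called, 2383 higher and 2597 lower. The count was 2529 and 2384 without replicates 1 and 2 labelled RanG22V D0.

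The comparison of RanG22V D0 with RanT27N D0 sets, by its labels, the lines side by side before darkness. Its file headers are RanG22V D3 and RanG22V D0, which would make it the change in darkness within the RanG22V line. The genes called higher in the pair labelled RanG22V D0 included members of the starvation, senescence, autophagy and chlorophyll breakdown lists. Those called lower included members of the photosynthesis, jasmonate, glucosinolate, flavonoid and salicylic acid lists. None of these lists kept its call with an estimated correlation. ASN1 was 1050-fold higher in the pair labelled RanG22V D0 (log2 fold change 10.03 ± 0.88, adjusted p = 0.000395 by edgeR, n = 2), and 16 of 22 dark and starvation genes were higher, also 16 adjusted over the list alone (median 3.18, camera adjusted p = 1.03e-11, and adjusted p = 0.119 with an estimated correlation). Calvin cycle genes were lower in 18 of 21 cases (19 lower and 1 higher adjusted over the list alone, median -3.53, camera adjusted p = 2.38e-10, and adjusted p = 0.228 with an estimated correlation). RBCS2B was 94.5-fold, RBCS3B 42.1-fold and PRK 21.3-fold lower. Light harvesting and photosystem genes were lower in 27 of 48 cases (41 adjusted over the list alone, camera adjusted p = 6.87e-13, and adjusted p = 0.228 with an estimated correlation). Senescence genes were higher in 13 of 25 cases and lower in 2 (15 and 3 adjusted over the list alone, camera adjusted p = 4.83e-05, and adjusted p = 0.119 with an estimated correlation) and autophagy genes higher in 15 of 24 (16 adjusted over the list alone, camera adjusted p = 2.26e-08, and adjusted p = 0.228 with an estimated correlation). Chlorophyll synthesis genes were lower in 9 of 16 (11 adjusted over the list alone, camera adjusted p = 4.18e-05, and adjusted p = 0.172 with an estimated correlation), glucosinolate genes in 10 of 14 (14 adjusted over the list alone, camera adjusted p = 2.54e-07, and adjusted p = 0.119 with an estimated correlation) and flavonoid genes in 8 of 12 (12 adjusted over the list alone, camera adjusted p = 7.5e-06, and adjusted p = 0.228 with an estimated correlation). Nitrogen remobilisation genes were higher in 6 of 13 and lower in 3, also adjusted over the list alone (camera adjusted p = 0.0259, and adjusted p = 0.228 with an estimated correlation). Of 13 chlorophyll breakdown genes 8 were higher and 3 lower (9 and 3 adjusted over the list alone, camera adjusted p = 0.0011, and adjusted p = 0.228 with an estimated correlation). MES16 was 41.8-fold and PPH, the pheophytinase gene, 6.14-fold higher.

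Salicylic acid genes were lower in 8 of 29 cases and higher in 2 (15 and 2 adjusted over the list alone, median -1.97, camera adjusted p = 0.0011, and adjusted p = 0.228 with an estimated correlation). PR5 was 88.6-fold, DLO1 27.5-fold and EDS5 11.7-fold lower, UGT74F2 was 20.2-fold higher, and PR1 was not called at 190.3 ± 154.8 against 428.6 ± 338.5 CPM. In the jasmonate list 8 of 18 were lower (12 adjusted over the list alone, camera adjusted p = 2.43e-05, and adjusted p = 0.228 with an estimated correlation). AOC2 was 101.3-fold, JAZ5 14.3-fold and LOX2 12.1-fold lower. GLYI4, a glyoxalase gene, was at 3079 ± 772.5 CPM against 0.0197 CPM, and BGLU30, a β-glucosidase gene induced in darkness, at 2094 ± 91.6 against 0.198 ± 0.112 CPM. AT5G46960, PDE337 and AT2G03850 had 0 counts in the pair labelled RanT27N D0 and were at least 921.3-, 700.9- and 627.5-fold higher. RANGAP1 was 7.27-fold and RANBP1B, a Ran-binding protein gene, 2.08-fold lower, 2 of 18 and also 2 adjusted over the list alone. RAN1, RAN2 and RAN3 were not called, with log2 fold changes of 0.58 ± 0.37, 0.76 ± 0.28 and 0.17 ± 0.25. In all 3782 genes were called, 1772 higher and 2010 lower, with 1641 and 1698 without replicates 1 and 2 labelled RanG22V D0 and 2074 without replicate 1 labelled RanT27N D0.

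The comparison of RanG22V D3 with RanT27N D3 asks, by its labels, how the lines differ after darkness. Its file headers are RanT27N D3 and RanT27N D0, which would make it the change in darkness within the RanT27N line. The genes called lower in the pair labelled RanG22V D3 included members of the photosynthesis, jasmonate, glucosinolate and flavonoid lists, and those called higher some of the senescence and starvation lists. With an estimated correlation 0 of the lists were called. SAG12 was at 288.9 ± 212 against 0.254 ± 0.275 CPM (log2 fold change 10.09 ± 1.61, adjusted p = 0.00652 by edgeR, n = 2). OSM34, an osmotin gene, was 671.1-fold higher, and RLP22 and AT4G33720, with 0 counts in the pair labelled RanT27N D3, at least 109.9-fold and 84.7-fold higher. Calvin cycle genes were lower in 17 of 21 cases (18 adjusted over the list alone, median -2.55, camera adjusted p = 2.77e-10, and adjusted p = 0.463 with an estimated correlation). GAPB was 31.2-fold, RBCS3B 15.4-fold, PRK 10.9-fold and PGK1 5.53-fold lower. Jasmonate genes were lower in 13 of 18 cases (15 adjusted over the list alone, median -4.05, camera adjusted p = 2.77e-10, and adjusted p = 0.463 with an estimated correlation). JAZ5 was 144.1-fold, JAZ8 76.5-fold, AOC2 67.3-fold and JAZ7 48.7-fold lower.

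Light harvesting and photosystem genes were lower in 15 of 48 cases (24 adjusted over the list alone, camera adjusted p = 2.32e-09, and adjusted p = 0.463 with an estimated correlation), glucosinolate genes in 6 of 14 (11 adjusted over the list alone, camera adjusted p = 4.53e-05, and adjusted p = 0.463 with an estimated correlation) and flavonoid genes in 4 of 12 (8 adjusted over the list alone, camera adjusted p = 0.000275, and adjusted p = 0.463 with an estimated correlation). PSBS was 29.7-fold, CYP79B3 14.9-fold and CHS, chalcone synthase, 127.4-fold lower. Dark and starvation genes were higher in 5 of 22 cases (7 adjusted over the list alone, median 0.75, camera adjusted p = 0.00103, and adjusted p = 0.463 with an estimated correlation). ASN1 was 117.1-fold, BGLU30 28.1-fold and GDH2 5.61-fold higher. Autophagy genes were higher in 3 of 24 (6 adjusted over the list alone, camera adjusted p = 0.00103, and adjusted p = 0.531 with an estimated correlation), chlorophyll synthesis genes lower in 4 of 16 (5 adjusted over the list alone, camera adjusted p = 0.0107, and adjusted p = 0.463 with an estimated correlation), and salicylic acid genes lower in 3 of 29 and higher in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.00587, and adjusted p = 0.463 with an estimated correlation). Senescence genes went both ways, 4 higher and 4 lower of 25 (7 and 6 adjusted over the list alone, camera adjusted p = 0.319). WRKY45 was 15.1-fold and SAG13 6.06-fold higher and SAG14 5.03-fold lower. NdhM and FLA1 had 0 counts in the pair labelled RanG22V D3 and were at least 189.7-fold and 90.2-fold lower. SUC2 was 11.8-fold and ATML1 3.11-fold lower, and RANGAP1 4.05-fold lower, while RAN1 and RAN3 had log2 fold changes of -0.28 ± 0.37 and 0.17 ± 0.25 and were not called. In all 2324 genes were called, 838 higher and 1486 lower. The count was 630 and 486 without replicates 1 and 2 labelled RanG22V D3, 915 and 1130 without those labelled RanT27N D3, 3709 without a filter and 4146 by DESeq2.

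The differences between the labelled lines on the 2 days share no library. Under the file headers they are the differences between D3 and D0 within RanG22V and within RanT27N. Of the genes called in both, 533 were higher in both (69.1 for independent lists) and 913 lower in both (139.1 for independent lists), and 10 went opposite ways. Across the 21475 genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.593 and Spearman's rho = 0.568.

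The interaction asks whether the change from D0 to D3 differed between the lines as labelled. It was called for 45 genes, 4 with a higher and 41 with a lower fold change in RanG22V than in RanT27N. DIN4 differed by a log2 of -4.37 ± 0.58 (adjusted p = 0.0239 by edgeR), with 223.7 and 16.5 CPM in RanG22V D0 and D3 and 6.24 and 9.49 CPM in RanT27N D0 and D3. WRKY6 differed by -3.19 ± 0.49 (adjusted p = 0.0454). The chaperone gene CRT1a (3.08 ± 0.40) and the disulfide isomerase gene UNE5 (2.50 ± 0.36), both of the endoplasmic reticulum, stood at 231.8 and 184.7 CPM in the pair labelled RanT27N D0 and at 28.9 to 62.5 CPM in the other 4 pairs. The dark and starvation list had a median difference of -2.56, with 1 of 22 called (11 adjusted over the list alone, camera adjusted p = 9.99e-11, and adjusted p = 0.224 with an estimated correlation). The count of 45 was 4 and 19 without replicates 1 and 2 labelled RanG22V D0, 6 and 1 without those labelled RanG22V D3, 26 and 13 without those labelled RanT27N D0, 3 without replicate 2 labelled RanT27N D3, 135 and 123 without those labelled Col D0. It reached 109 with only the 8 libraries of the lines, 568 without a filter and 719 by DESeq2. A further 11 lists differed with the preset correlation and 0 with an estimated one, with adjusted p = 0.294 the lowest of these 11 with an estimated correlation.

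The comparison of RanT27N D3 with Col D0 differs in both line and day by its labels. The file headers make it RanT27N D0 against Col D0, which differ in line only. The quasi-likelihood test of edgeR called 0 genes, with 867 genes at an unadjusted p below 0.05, 48 called by DESeq2 and 24 called without a filter. ASN1 was at 0.228 ± 0.153 against 1.12 ± 0.320 CPM, SAG12 at 0.254 ± 0.275 against 0.574 ± 0.811 CPM and RBCS1A at 3968 ± 1962 against 3986 ± 14.9 CPM. RAN1 was 4.12-fold higher in the fit (log2 fold change 2.04 ± 0.39, adjusted p = 0.575) and RAN3 2.00-fold (1.00 ± 0.25, adjusted p = 1), both called by DESeq2 and not by edgeR. Ran and transport genes had a median of 0.23 with 0 of 18 called (4 higher adjusted over the list alone, camera adjusted p = 0.000276, and adjusted p = 0.993 with an estimated correlation), and abscisic acid genes a median of 0.83 with 0 of 15 called (1 higher adjusted over the list alone, camera adjusted p = 0.00562, and adjusted p = 0.993 with an estimated correlation). The Calvin cycle median was 0 and the dark and starvation median -0.10, with 0 called in either list and 0 adjusted over the list alone. Leaving out replicate 1 labelled Col D0 gave 1 call.

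The comparison of RanG22V D3 with Col D0 differs in line and day by its labels. It also does so by the file headers, which make it RanT27N D3 against Col D0. The genes called lower in the pair labelled RanG22V D3 included members of the photosynthesis, jasmonate, flavonoid and salicylic acid lists, and chlorophyll breakdown genes were called in both directions. No list was called with an estimated correlation. NYE1 was 5.30-fold, NYE2 11.5-fold, MES16 11.2-fold and CYP89A9 16.4-fold higher (log2 fold changes 2.41 ± 0.37 to 4.04 ± 0.70, adjusted p = 0.00617 for NYE1 by edgeR, n = 2), with 4 of 13 higher and 3 lower (5 and 3 adjusted over the list alone). Calvin cycle genes were lower in 17 of 21 cases (18 adjusted over the list alone, median -2.73, camera adjusted p = 1.32e-10, and adjusted p = 0.37 with an estimated correlation), jasmonate genes in 13 of 18 (16 adjusted over the list alone, median -3.56, camera adjusted p = 5.15e-09, and adjusted p = 0.37 with an estimated correlation) and flavonoid genes in 7 of 12 (10 adjusted over the list alone, median -5.98, camera adjusted p = 1.79e-05, and adjusted p = 0.37 with an estimated correlation). GAPB was 28.4-fold, JAZ5 102.9-fold, OPR3 36.5-fold and DFR, of anthocyanin synthesis, 187.9-fold lower.

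Salicylic acid genes were lower in 7 of 29 cases and higher in 1 (10 and 1 adjusted over the list alone, median -1.92, camera adjusted p = 0.000991, and adjusted p = 0.37 with an estimated correlation). GRX480 was 72.6-fold, WRKY18 15.6-fold, CBP60G 11.2-fold and NPR3 5.78-fold lower. In the Ran and transport list RAN1 (3.39-fold), RAN2 (4.69-fold) and RAN3 (2.25-fold) were higher and RANGAP1 3.31-fold lower, 4 of 18 higher and 1 lower, also 4 and 1 adjusted over the list alone (camera adjusted p = 0.00596, and adjusted p = 0.37 with an estimated correlation). Dark and starvation genes were higher in 5 of 22 cases (6 adjusted over the list alone, camera adjusted p = 0.0014, and adjusted p = 0.37 with an estimated correlation) and autophagy genes in 3 of 24 (4 adjusted over the list alone, camera adjusted p = 0.000999, and adjusted p = 0.472 with an estimated correlation). Light harvesting genes were lower in 15 of 48 (22 adjusted over the list alone, camera adjusted p = 1.39e-06, and adjusted p = 0.472 with an estimated correlation), glucosinolate genes in 4 of 14 (11 adjusted over the list alone, camera adjusted p = 6.38e-05, and adjusted p = 0.37 with an estimated correlation) and chlorophyll synthesis genes in 4 of 16, also 4 adjusted over the list alone (camera adjusted p = 0.0344, and adjusted p = 0.377 with an estimated correlation). SAG12 was 503.6-fold higher, while the senescence list as a whole had a median log2 fold change of 0.38. HFR1, a transcription factor gene of the shade response, was at 32.6 ± 3.42 against 0.0499 CPM. MSRB6 had 0 counts and was at least 83.4-fold lower. In all 2404 genes were called, 890 higher and 1514 lower. The count was 642 and 549 without replicates 1 and 2 labelled RanG22V D3. It reached 1125 with only the 4 libraries compared, 3793 without a filter and 4279 by DESeq2.

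Comparisons with Col D0 share its 2 libraries, which were not divided between the comparisons, so part of any overlap between them may come from those libraries. RanG22V D0 and RanG22V D3 against Col D0 had 677 genes higher in both (98.8 for independent lists, 0 in 20 simulations of unchanged groups) and 1144 lower in both (183.1 for independent lists, 0 in the simulations). Their fold changes correlated across genes with r = 0.732 and a covariance of 3.574, against 0.50 and 0.401 in the simulations. RanT27N D0 and RanG22V D0 against Col D0 had 36 genes higher in both (5.8 for independent lists, 0 in the simulations), with r = 0.473 and a covariance of 1.514, against 0.51 and 0.40. Groups simulated as unchanged are rarely called, so a count of 0 was nearly fixed in advance. It cannot show how much of an overlap the shared libraries gave.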

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

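In this part the test on the lowest Calvin cycle medians and the count of libraries that the labelled line and the header divide differently were chosen after the result was seen. The change from D0 to D3 differed between the labelled lines for 45 genes by the interaction term. The log2 differences of fold change, RanG22V minus RanT27N, were 4.44 for MLP43, 4.03 for AT2G47480, 3.08 for CRT1a, 2.50 for UNE5, -9.93 for GLYI4, -8.77 for AT1G09500, -8.18 for GDPD2, -7.99 for AT5G12340, -3.19 for WRKY6 and -4.37 for DIN4. With the preset correlation 12 lists differed, with median differences of -2.56 for dark and starvation, -1.40 for chlorophyll breakdown, -0.93 for autophagy, -0.89 for abscisic acid, -0.73 for nitrogen remobilisation, -0.68 for jasmonate, -0.63 for senescence, -0.35 for ethylene, 0.65 for the Calvin cycle, 0.96 for chlorophyll synthesis, 0.97 for light harvesting and 1.7 for glucosinolates, and 0 of these lists kept the call with an estimated correlation. With the names of the file headers the interaction has the same genes with the sign turned.

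The labels and the names in the file headers disagreed for 8 of 10 libraries, and the comparison set beforehand asked whether dark and starvation genes differ between the pairs labelled RanT27N D3 and RanT27N D0. Their median log2 difference was 0.30, against 3.18 between the pairs labelled RanG22V D0 and RanT27N D0, which is what file pairs attached to the wrong sample labels would give. Darkness acting in the libraries labelled D3 of both lines would lower Calvin cycle genes in RanT27N D3, and the lowest of the 4 library-by-library medians against RanT27N D0 was -0.67, above the -1 set as the bound, where the pair labelled RanG22V D0 gave -2.79 to -4.52. That the labels are right and the lines set the pattern, RanG22V showing it in the light and RanT27N lacking it after darkness, cannot be told apart from wrong labels, because the labelled line and the day of the header differ in their division for 0 of the 8 libraries of the lines. An exchange of only the pairs labelled RanG22V D0 and RanT27N D3 would also put the pattern in the D3 groups, and RAN3, higher in the pairs labelled RanT27N D3 and RanG22V D3, divides the libraries by line under the headers and under that exchange alike, so the data do not show which line is which.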

How the results depend on the processing

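The replicate term in 6 libraries and the fit without ribosomal RNA and organelle genes were chosen after seeing the data. DESeq2 size factors and the fit without ribosomal RNA and organelle genes left all 9 counts of called genes within 1.5 times. With an estimated correlation 0 of the 73 list calls by camera were kept. Fry, which tests a list on its own, gave dark and starvation adjusted p = 0.00069 in RanG22V D0 vs RanT27N D0. In RanG22V D3 vs RanG22V D0 it gave that list 0.00524 and light harvesting 0.193. The other organs, with 0 members called, had 0.00259 and 0.00768 by fry in these comparisons. Without a filter on low counts 7 of 9 counts moved, to 563 for RanT27N D3 vs RanT27N D0, 2107 for RanG22V D3 vs RanG22V D0, 391 for RanT27N D0 vs Col D0, 3709 for RanG22V D3 vs RanT27N D3, 568 for the interaction, 24 for RanT27N D3 vs Col D0 and 3793 for RanG22V D3 vs Col D0. By DESeq2 the same 7 comparisons in this order gave 563, 2583, 402, 4146, 719, 48 and 4279. DESeq2 made 32.6% false calls on simulated counts of another comparison, RanG22V D0 vs RanT27N D0, and its share in these 7 was not tested. The stricter filter gave 34 for RanT27N D0 vs Col D0. Fitting only the libraries compared gave 0 for RanT27N D3 vs RanT27N D0, 3607 for RanG22V D3 vs RanG22V D0, 0 for RanT27N D0 vs Col D0, 1125 for RanG22V D3 vs Col D0 and 109 for the interaction (8 libraries). The replicate numbers do not pair the libraries across all groups, as replicate differences correlated by -0.008 to 0.31 between groups, over 0.1 only among Col D0, RanT27N D0 and RanT27N D3 (0.124, 0.31 and 0.188). The replicate term gave 83 for the interaction. In those 6 libraries it gave 44 for RanT27N D3 vs RanT27N D0, with 26 of the 74 genes called in both fits, and 27 for RanT27N D0 vs Col D0, with 16 of 53, and 13 calls of named genes were made and 10 were not. These were AT5G47590, AT5G16250, SQE6, CYP81F2 and AT5G56590, all 5 genes called higher in RanT27N D3 vs RanT27N D0, AT2G44240, FMO1, SDR4 and WRKY75 in the same comparison, and AT2G04050 in RanT27N D0 vs Col D0. Under the group names of the file headers, which rename the same fit, the counts were 2324 for RanT27N D3 vs RanT27N D0, 3782 for RanG22V D3 vs RanG22V D0, 0 for RanT27N D0 vs Col D0, 53 for RanG22V D0 vs Col D0, 74 for RanG22V D0 vs RanT27N D0, 846 for RanG22V D3 vs RanT27N D3, 2404 for RanT27N D3 vs Col D0 and 4980 for RanG22V D3 vs Col D0. Apart from the differing libraries and genes in these fits, the cause was not tested.

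Leaving out each library in turn moved 46 of 90 counts by over 1.5 times, and 636 calls of named genes were lost and 2884 kept. The counts ran from 0 to 180 for RanT27N D3 vs RanT27N D0, 27 to 1464 for RanG22V D3 vs RanG22V D0, 0 to 46 for RanT27N D0 vs Col D0, 2384 to 4899 for RanG22V D0 vs Col D0, 1641 to 4658 for RanG22V D0 vs RanT27N D0, 486 to 3191 for RanG22V D3 vs RanT27N D3, 1 to 135 for the interaction, 0 to 1 for RanT27N D3 vs Col D0 and 549 to 2533 for RanG22V D3 vs Col D0. List medians for RanT27N D0 vs Col D0 depended on the Col D0 library left out, with -1.07 for light harvesting and 1.51 for flavonoids without replicate 1, and 1.14 and -1.85 without replicate 2. For RanT27N D3 vs Col D0 without replicate 1 labelled Col D0, light harvesting had -0.52 and autophagy -0.37, against 1.58 and 0.46 without replicate 2. These lists were not called with all libraries, and the cause was not tested. In the simulations, with 2 libraries per group and few genes changed, most changes of 4-fold or less were missed. This need not hold where many more genes differ. For RanG22V D0 vs Col D0, 4846 of the 4980 called genes reached 2-fold, so some smaller changes were called there.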

Other observations

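The tests in this part were chosen after the results were seen. In the pairs labelled Col D0, RanT27N D0 and RanT27N D3, the clock gene GI was at 0, 0.0462 and 1.02 CPM in replicate 1 and at 66.6, 22.9 and 75.5 CPM in replicate 2. PRR7 was higher in replicate 2 by log2 differences of 3.97, 4.33 and 4.31 and PRR9 by 3.30, 3.24 and 4.35. CCA1, a morning gene, differed by -3.81 in Col D0 but by 2.27 and 2.64 in the other 2 pairs. In the pairs labelled RanG22V D0 and RanG22V D3 GI differed by -1.15 and 0.92 and PRR7 by -0.81 and 1.38. By the file headers the first 3 pairs were sampled on day 0 and these 2 after darkness. Light harvesting and photosystem genes had median differences, replicate 2 minus replicate 1, of 2.2, 0.62 and 1.01 in the first 3 pairs and -0.49 and -0.29 in the other 2. Median differences of the flavonoid list in the first 3 pairs were -3.43, -0.43 and -1.4, and those of the heat shock list -3.49, 3.53 and -0.19.

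The replicate differences of the 13 clock genes correlated across genes, which are not independent replicates, by 0.76 to 0.91 between each 2 of the 3 pairs and by 0.56 to 0.75 between these and the pair labelled RanG22V D3, which restates the pattern. With the pair labelled RanG22V D0 the correlations were -0.3 to 0.04. A larger share of photosynthetic cells in replicate 2 would raise Calvin cycle genes too, and their highest median difference over the 3 pairs was -0.13, below the 0.62 that was the lowest for light harvesting genes. Whether the replicates differed in harvest time, light or growth conditions was not tested.

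The salicylic acid list had a median log2 fold change of 1.05 between the pairs labelled RanT27N D0 and Col D0, with 2 of 29 genes called and adjusted p = 0.485 with an estimated correlation. Between the 2 libraries labelled Col D0 this list differed by a median of -0.7, replicate 2 minus replicate 1. The 4 library-by-library medians between the pairs were all positive, from 0.73 to 2.05. The list was thus higher in RanT27N D0 with either library of each pair, though a single library may have set part of the size. PR1 was likewise at 80.8 and 299.8 CPM and FMO1 at 8.49 and 14.9 CPM in the pair labelled RanG22V D0. The file headers give that pair as the same line as the pair labelled RanT27N D0. The whole list in RanG22V D0 had a median log2 fold change of -0.23 against Col D0. DLO1 and PR5, the 2 members called in RanT27N D0 vs Col D0, were called lower in RanG22V D0 than in RanT27N D0. EDS5 was called lower in RanG22V D0 than in Col D0. Neither harvest time nor an effect of the line nor an infection or stress unrelated to it was tested, since no second set of plants is given for a group.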
